A study of Caenorhabditis elegans with 16 samples.

How the data were processed

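Per the labels, polyadenylated RNA of starved L1 larvae was extracted with TRIzol, an ERCC spike-in mix was added per amount of total RNA, and libraries were made with the NEBNext Ultra II kit. Per the submitters' processing notes, reads were mapped with Bowtie 1.2.2 to the WS273 genome, keeping 1 alignment for reads with at most 2 places (settings -k 1 and -m 2), and assigned to genes of the WS273 canonical gene set with HTSeq 0.11.2. The strand setting is not stated. The deposited file of each library holds counts per gene (unit: counts, unscaled), with 46911 genes and 5 HTSeq summary entries for reads without a gene. The authors' deposited table of CPM holds counts scaled by the sum of all entries, summary entries included, without TMM factors, for genes above 1 CPM in at least 4 libraries. In the 12 columns whose names match 1 library each, the deposited count table equals the files per library in 562932 of 562932 values. The authors' deposited interaction table, made with edgeR 3.24.4, holds log2 fold changes and mean log2 CPM, a score (the quasi-likelihood F) and a p-value with its adjusted value. The processing notes name a restriction to protein-coding genes, and the authors' deposited table of 12690 genes also holds genes of other classes.

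The deposited counts of the 16 libraries were analysed here. Reads that did not align made up 35.7% to 38.2% of each library and all reads without a gene 40.4% to 42.4%, of which 1.99% to 3.07% lay outside genes and 1.84% to 2.59% were ambiguous (percent of all reads). Counts assigned to genes ranged from 14033534 to 24903552 per library, and between 20731 and 24943 genes had at least 1 count. The 10 most abundant genes took 10.5% to 14.0% of gene counts. Gene symbols and coordinates came from Ensembl 115 (WBcel235), which matched 44053 of the gene identifiers. The annotation is later than the one used for counting.

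Genes with at least 1 CPM in at least 4 libraries were tested, 14058 in all. Libraries were scaled with TMM factors, and 1 quasi-likelihood model with robust dispersion over the 4 groups was fitted in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), from which 6 contrasts were taken: the irld mutant and the daf-2 mutant against wild type, the triple mutant against the daf-2 mutant, the irld mutant and wild type, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 CPM values use a prior count of 2, and fold changes use edgeR's default prior count. Standard errors of fold changes are approximated as the size of the log2 fold change over the square root of F. Group values are CPM with SD, n = 4 libraries. For genes with few counts in a group the ratio of summed counts is given with a 95% counting interval.

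Gene lists (41 in all) covered DAF-16 targets, stress responses, detoxification, insulin signalling and the irld family, the cuticle and molting, the cell cycle, translation, metabolism, degradation, immunity, neuropeptides, histones, and markers of tissues and stages. They were tested with camera at its preset correlation of 0.01, called at an adjusted p under 0.05 over the lists of a contrast, and again with camera's estimated correlation and with fry. Members were also adjusted over their list alone. Lists held between 10 and 241 names, of which at least 5 were tested. The names daf-21, ram-4, T24B8.5, cdr-5 and elt-5 were not matched. The design, the gene lists and the alternatives below, unless stated, were chosen before the data were examined.

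Genes are named by a fixed rule: daf-2, irld-39 and irld-52 in every library; for each contrast the 8 called genes with the largest change in each direction (3 for the triple mutant against the irld mutant and wild type) with a mean of at least 5 CPM and, except in the interaction, no overlap between the groups' libraries; from each list with at least 2 called members up to 4 with the smallest adjusted p; and sod-3, mtl-1, hsp-12.6, daf-16, daf-28 and ins-7 in each contrast. The text names some of the genes the rule gives.

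The alternatives were the replicate number as a block, DESeq2 size factors, DESeq2 1.42.0 Wald tests, no filter on low counts, edgeR's own filter, a test against a 1.5-fold change, only the groups compared, each triple mutant line left out, and each library left out. Chosen after seeing the data were protein-coding genes alone, library sizes of all reads without TMM factors, the mean of a full early embryo list as a term, and leaving out 3 libraries low on the first component. The full list included genes already seen to vary in these data. Without those it held 21 names (20 tested), and this part gave the values reported for 20 early embryo genes. No 2 replicates had identical counts. In a test on simulated data, 200 genes were changed by 1.5-fold, 2-fold or 4-fold: 17.9%, 58.2% and 84.8% were called between the irld mutant and wild type, and 19.4%, 62.7% and 83.3% between the daf-2 mutant and wild type, with 4 and 6 false calls of 13858 unchanged genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Scaling by spike-ins was not analysed here, since the count files hold no entry for them.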

Results

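Messenger RNA was sequenced from whole Caenorhabditis elegans larvae of the L1 stage that had hatched without food and were collected 12 hours after hatch, 24 hours after the embryos were prepared by bleaching, at 20 °C. Each library came from 10000 larvae. The 16 libraries form 4 groups of 4 biological replicates: wild type (strain N2), a mutant of irld-39(duk1) and irld-52(duk17) (the irld mutant), a mutant of daf-2(e1370), and a triple mutant that carries all 3 alleles. The triple mutant is represented by a pair of independent lines, LRB457 and LRB458, with 2 libraries each. The gene daf-2 encodes the insulin/IGF receptor of the worm, and the irld genes encode proteins with domains like those of the insulin and EGF receptors. The counts assigned to genes were 15263722, 16096121, 14033534 and 14340531 in wild-type replicates 1 to 4. They were 15828107, 15239744, 15756335 and 18089336 in the irld mutant and 16986010, 15616627, 16434831 and 17632908 in the daf-2 mutant. In the triple mutant they were 15758701 and 15527842 for the LRB457 libraries and 19894494 and 24903552 for the LRB458 libraries. Group levels below are given in CPM (counts scaled to library size) as mean ± SD over the 4 libraries of a group, and changes as log2 fold change ± standard error.

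The first principal component of log2 CPM held 42.4% of the variance. Wild-type libraries lay at -35.5 ± 2.42 on it and irld libraries at -35.6 ± 2.98 (SD, n = 4 each). The daf-2 libraries lay at 26.9 ± 25.9 and the triple mutant libraries at 44.2 ± 18 (SD, n = 4 each). Within the daf-2 group, replicates 2 and 4 stood at 6.90 and 4.36, against 38.1 and 58.1 for replicates 1 and 3. Among the triple mutant libraries, replicate 1 of LRB458 stood at 19, against 46.2, 50.2 and 61.4 for the others. Wild-type libraries, close on this component, differed elsewhere. The chi-square per gene between counts of replicates was 88.1, 74.2 and 100.5 for wild-type replicate 3 against 1, 2 and 4. Wild-type replicates 1 and 4 gave the lowest value of any pair. Outside wild type the highest was 46.3 (daf-2 replicates 3 and 4). On the second component, wild-type replicates 2 and 3 stood at -23.5 and -23.3, against 7.28 and 3.49 for 1 and 4. The daf-2 libraries spanned -32.6 to 46.1 there. The mean log2 CPM of the glutathione S-transferase and cytochrome P450 genes was 2.72 ± 0.20 in wild type, 2.68 ± 0.12 in the irld mutant, 3.41 ± 0.62 in the daf-2 mutant and 3.84 ± 0.66 in the triple mutant (SD, n = 4 each). That of 20 early embryo genes, a list chosen after the data were seen, was 3.05 ± 0.28, 2.76 ± 0.38, 2.51 ± 0.67 and 2.44 ± 0.33 in the same order.

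**Figure D1:**
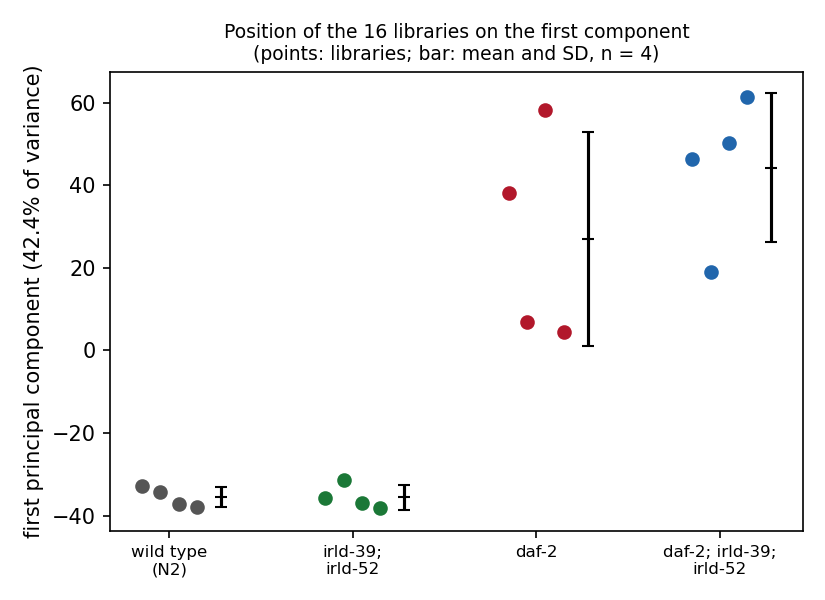
Position of each library (points) on the first principal component of log2 CPM, by genotype, with the group mean and SD (n = 4). The wild-type and irld libraries lie between -38.3 and -31.4, and the 8 libraries with daf-2(e1370) between 4.36 and 61.4.

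The genes that carry the alleles were looked at before any other. The gene daf-2 (WBGene00000898, chromosome III, 2994514 to 3040846, WBcel235) stood at 408 ± 165.5 CPM in wild type, 511 ± 86.1 in the irld mutant, 451 ± 27.4 in the daf-2 mutant and 413 ± 34.1 in the triple mutant. None of the contrasts called it, with log2 fold changes of 0.32 ± 0.22 in the irld mutant, 0.14 ± 0.22 in the daf-2 mutant and 0.01 ± 0.22 in the triple mutant, all against wild type (adjusted p = 0.708, 0.692 and 0.976). It was also not called between the triple mutant and the daf-2 mutant (-0.13 ± 0.22, adjusted p = 0.948) or the irld mutant (-0.31 ± 0.22, adjusted p = 0.373). The genes irld-39 (WBGene00010415, chromosome IV, 16233148 to 16236555) and irld-52 (WBGene00012043, chromosome V, 15779679 to 15781247) had between 1 and 12 counts in each library, too few to test. Over the 4 libraries of a group, irld-39 had 13 counts in wild type, 23 in the irld mutant, 13 in the daf-2 mutant and 26 in the triple mutant. For irld-52 these totals were 16, 20, 17 and 27 counts. Neither gene was tested, so these totals do not show whether the groups differ.

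The question for the irld mutant was what the irld-39 and irld-52 alleles change in larvae with normal daf-2. One gene differed from wild type: ugt-64 (WBGene00015577, chromosome V, 3503080 to 3506352), which encodes a UDP-glycosyltransferase, an enzyme class that attaches sugars to small molecules. Its level was 4.39 ± 0.379 CPM in wild type and 9.12 ± 0.683 CPM in the irld mutant, a log2 fold change of 1.05 ± 0.13 (adjusted p = 0.00549), with all 4 irld libraries above all 4 wild-type libraries. Target genes of DAF-16, the transcription factor that daf-2 signalling restrains, were not called: the superoxide dismutase gene sod-3 changed by -0.13 ± 0.24 (adjusted p = 0.903), the metallothionein gene mtl-1 by -0.65 ± 0.19 (0.690) and the small heat shock protein gene hsp-12.6 by -0.33 ± 0.26 (0.744). The same held for daf-16 itself (0.35 ± 0.15, adjusted p = 0.690) and for the insulin-like peptide gene daf-28 (-0.10 ± 0.42, adjusted p = 0.964). The insulin-like peptide gene ins-7 was too low to test in any contrast.

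Of 14058 tested genes, edgeR thus called 1 in the irld mutant, with 911 genes at an unadjusted p under 0.05 where chance alone gives 703. The irld and wild-type libraries did not overlap in 315 genes (2.24%), where chance gives 2.86%. Separation of the libraries alone therefore does not set ugt-64 apart. Genes are not independent, so neither count tests for an effect of the irld alleles. DESeq2 called 2 genes. Neither edgeR against a 1.5-fold change nor edgeR on the 8 libraries of these groups alone called any gene. Of the genes given a simulated 2-fold change between these groups, 58.2% were called, and of those given a 4-fold change 84.8%. The simulation changed 200 genes at once, which loosens the adjusted threshold, and drew the counts of each gene independently. These shares therefore do not give the power where few genes change. Among the fixed gene lists, 11 passed camera with its preset correlation, although none of their members was called and none of these lists passed with an estimated correlation. Lower as sets were ribosomal proteins (median -0.14, adjusted p = 7.43e-08; adjusted p = 0.717 with an estimated correlation), neuropeptides (median -0.24, 3.31e-07; 0.590) and collagens of the cuticle (median -0.27, 4.22e-07; 0.590). Oxidative phosphorylation, proteasome, immune effector, cell cycle and antioxidant genes were also lower as sets, and adjusted over the list alone 2 cell cycle genes were lower. In lists that did not pass, 2 C-type lectin genes and 1 metal gene were lower and 1 UDP-glycosyltransferase gene was higher when adjusted that way. The irld gene family (median 0.30, adjusted p = 0.00729; adjusted p = 0.437 with an estimated correlation), body muscle markers and molting genes were higher as sets. For the lists that passed camera and are given without values, adjusted p lay between 0.590 and 0.717 with an estimated correlation.

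The daf-2 mutant was compared with wild type to describe larvae with the daf-2 allele and without the irld alleles. Wild type, the irld mutant and the daf-2 mutant are 1 strain each. No comparison with them can by itself tell an allele effect from another difference between strains. Against wild type, 1121 genes were higher and 1088 lower in daf-2 larvae, and of these 397 were over 2-fold higher and 347 over 2-fold lower. This balance depends on processing: 1285 were higher and 953 lower with library sizes of all reads in place of TMM scaling, and 909 and 1254 with the full early embryo list as a term in the model. The largest increases included a pair of irld family genes, irld-53 (WBGene00021222, chromosome V, 2348215 to 2350325) and irld-35 (WBGene00018917, chromosome V, 2456176 to 2458286), with adjusted p = 4.22e-09 and 1.17e-09. For irld-53 the 4 daf-2 libraries held 2152 counts and the wild-type libraries 1 count, a depth-adjusted ratio of 1928 with a 95% counting interval from 346 to 76189. For irld-35 there were 2005 against 5 counts, a ratio of 359 (154 to 1108). The triple mutant, which also carries daf-2(e1370), held 9 counts of irld-53 and 16 of irld-35. Of all called genes, 639 of the 1121 higher and 705 of the 1088 lower were called the same way between the triple and the irld mutant. The uncharacterised gene H39E23.3 rose from 2.03 ± 0.598 to 154 ± 18.8 CPM (log2 fold change 6.23 ± 0.28, adjusted p = 1.17e-09), and catp-3, a gene of a P-type ATPase, from 3.35 ± 1.66 to 77.8 ± 41.8 CPM (4.53 ± 0.49, 2.74e-05). The other large increases varied widely between daf-2 libraries: F57H12.6 reached 65.7 ± 97.1 CPM (6.50 ± 1.55, adjusted p = 0.0114), C02E7.7 50.7 ± 60.6 CPM (5.07 ± 1.3, 0.0168) and ugt-41 7.06 ± 8.24 CPM (4.55 ± 0.99, 0.00649). Without daf-2 replicate 3 these changes were 4.64, 3.98 and 3.33. The glutathione S-transferase gene gst-33 changed by 4.78 ± 1.39 (adjusted p = 0.0318), a call that was lost without wild-type replicate 1, 2, 3 or 4 or daf-2 replicate 3, where the change ranged from 2.80 to 5.17 and adjusted p reached 0.147.

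The largest decreases in daf-2 larvae were in dod-24, a gene named for lying downstream of daf-16, which fell from 35.9 ± 11.5 to 0.586 ± 0.390 CPM (-5.92 ± 0.43, adjusted p = 6.56e-07), and in the chemoreceptor-like gene srw-85, from 122 ± 42.9 to 2.195 ± 0.705 CPM (-5.81 ± 0.30, 6.49e-09). The saposin-like genes spp-6 and spp-2 fell (-3.54 ± 0.33 and -3.27 ± 0.35; adjusted p = 2.91e-06 and 1.86e-05), as did the cathepsin B-like protease genes cpr-5 and cpr-1 (-2.76 ± 0.17 and -2.74 ± 0.43; 4.06e-08 and 6.12e-04). F47B8.10 and F21C10.9 changed by -4.11 ± 0.46 and -3.24 ± 0.64 (adjusted p = 3.21e-05 and 0.00341); without daf-2 replicate 3 the change of F47B8.10 was -4.86.

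Of the genes described as induced by DAF-16, 7 of 23 rose and 2 fell, the same numbers when adjusted over the list alone, and the list as a set did not pass (adjusted p = 0.127). The superoxide dismutase gene sod-3 rose from 16.38 ± 6.04 to 40.4 ± 5.07 CPM (1.301 ± 0.24, adjusted p = 0.00155) and the catalase genes ctl-1 and ctl-3 rose by 0.86 ± 0.17 and 0.93 ± 0.19 (0.00243 and 0.00358). In contrast, hsp-12.6 fell from 168 ± 57.9 to 60.3 ± 9.54 CPM (-1.48 ± 0.27, 0.00148). Neither mtl-1 (0.15 ± 0.19, adjusted p = 0.623), daf-16 (0.17 ± 0.15, 0.480) nor daf-28 (0.13 ± 0.42, 0.857) was called. Of 5 tested genes described as repressed when DAF-16 is active, 2 fell, also when adjusted over the list alone: dod-24 and dod-22 (-4.03 ± 0.34, 1.25e-06). As a set these had an adjusted p = 0.0123 by camera and adjusted p = 0.216 with an estimated correlation.

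Some genes of the cuticle and of detoxification rose and fewer fell. Of the collagen genes, 28 rose and 7 fell (32 higher and 8 lower when adjusted over the list alone), among them col-50 (3.69 ± 0.35), col-166 (1.75 ± 0.19) and col-103, which rose from 1159 to 2941 CPM. The set passed camera (adjusted p = 6.36e-04; adjusted p = 0.602 with an estimated correlation). Of 66 cytochrome P450 genes, which encode oxidising enzymes, 14 rose and 2 fell (15 higher and 2 lower when adjusted over the list alone), with cyp-33C1 at 2.59 ± 0.29 and cyp-33C2 at 2.97 ± 0.35 (set adjusted p = 3.41e-04; adjusted p = 0.602 with an estimated correlation). Of 57 UDP-glycosyltransferase genes, 11 rose, ugt-6 (1.87 ± 0.17) and ugt-64 (1.11 ± 0.13) among them, and 5 fell (13 higher and 5 lower when adjusted over the list alone; set adjusted p = 0.0483; adjusted p = 0.602 with an estimated correlation). Of 40 glutathione S-transferase genes, 11 rose and 3 fell (17 higher and 3 lower when adjusted over the list alone), with gst-3 higher (0.73 ± 0.14) and gst-27 lower (-1.41 ± 0.14), and the set did not pass (adjusted p = 0.0562). Of 23 molting and developmental timing genes, 4 rose and none fell (6 higher and 1 lower when adjusted over the list alone), with the transcription factor gene blmp-1 at 0.90 ± 0.19 (set adjusted p = 0.0276; adjusted p = 0.602 with an estimated correlation).

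Genes of lipid and sugar metabolism changed in both directions. Of 23 fatty acid synthesis genes, 2 rose and 7 fell (2 higher and 9 lower when adjusted over the list alone; set adjusted p = 0.00741; adjusted p = 0.602 with an estimated correlation). The fatty acid desaturase gene fat-2 fell from 1073 ± 224 to 289 ± 28.6 CPM (-1.89 ± 0.14, adjusted p = 3.71e-07), the desaturase gene fat-3 changed by -1.45 ± 0.13 and the elongase gene elo-5 by -3.61 ± 0.49. Of 27 fat breakdown genes, 5 rose and 4 fell (5 higher and 5 lower when adjusted over the list alone; set adjusted p = 0.884): among genes of lysosomal lipases, lipl-4 rose (3.94 ± 0.42) and lipl-5 fell (-1.95 ± 0.16). Of 19 gluconeogenesis, trehalose and glyoxylate genes, 7 rose and 2 fell, also when adjusted over the list alone (set adjusted p = 0.0562). The trehalose synthesis gene tps-1 rose (0.71 ± 0.16) and the genes of the trehalose-splitting enzymes tre-3 and tre-5 fell (-1.42 ± 0.13 and -2.21 ± 0.20).

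Autophagy, lysosomal, neuropeptide, histone and ribosomal protein genes were lower as sets at the preset correlation. None of 27 autophagy genes rose and 11 fell (13 when adjusted over the list alone), including the LC3-like gene lgg-2 (-0.73 ± 0.09) and epg-9 (-0.64 ± 0.11), with a set adjusted p = 6.36e-04 and adjusted p = 0.574 with an estimated correlation. None of 43 lysosomal genes rose and 12 fell (1 higher and 13 lower when adjusted over the list alone), such as the aspartyl protease gene asp-14 (-2.003 ± 0.23) and the DNase gene nuc-1 (-0.97 ± 0.15) (set adjusted p = 0.00204; adjusted p = 0.602 with an estimated correlation). Of the neuropeptide genes, 13 fell, such as flp-10 (-0.69 ± 0.14), and nlp-77 rose (1.03 ± 0.15) (1 higher and 12 lower when adjusted over the list alone; set adjusted p = 4.56e-06; adjusted p = 0.602 with an estimated correlation). Of 17 histone genes, 4 fell (5 when adjusted over the list alone), such as his-60 (-1.39 ± 0.23) and his-71 (-0.47 ± 0.11) (set adjusted p = 0.00436; adjusted p = 0.141 with an estimated correlation). The ribosomal protein set was lower (median -0.24, set adjusted p = 6.29e-07; adjusted p = 0.704 with an estimated correlation), with 3 of 78 genes called lower and none when adjusted over the list alone.

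The remaining lists of metabolism, stress and signalling did not pass as sets in the daf-2 mutant. Of 54 immune effector genes 9 rose and 14 fell (11 higher and 15 lower when adjusted over the list alone), and of 86 C-type lectin genes 4 rose and 17 fell (6 higher and 17 lower). The numbers higher and lower were 4 and 1 of 21 heat shock genes, 4 and 0 of 20 endoplasmic reticulum stress genes, 2 and 0 of 10 mitochondrial chaperone and protease genes, and 6 and 2 of 25 antioxidant genes. They were 1 and 2 of 21 insulin signalling genes, 2 and 1 of 21 insulin-like peptide genes, 2 and 1 of 15 irld family genes and 0 and 1 of 19 genes of other dauer pathways. The insulin-like peptide gene ins-27 rose (1.29 ± 0.14) and ins-17 fell (-0.51 ± 0.12). In the metal list, 2 of 13 rose and 4 fell, with the ferritin gene ftn-2 at -0.89 ± 0.11 and the metallothionein gene mtl-2 at -2.21 ± 0.34, and its median of 0.69 and mean of 0.51 were positive where its set test was negative. Cell cycle genes gave 4 and 2 of 28, oxidative phosphorylation 2 and 0 of 41, glycolysis 0 and 1 of 19, hypoxia 1 and 0 of 10 and the proteasome 0 and 0 of 33. Adjusted over the list alone, the counts were 6 higher and 2 lower for endoplasmic reticulum stress, 3 higher and 1 lower for mitochondrial chaperones, 7 higher and 2 lower for antioxidant, 3 higher and 1 lower for irld family, 7 higher and 2 lower for cell cycle and 3 higher and 4 lower for metal genes. They were 1 higher and 0 lower for oxidative phosphorylation and 0 higher and 0 lower for dauer pathway genes, and the same as above for the other lists of this paragraph. The median and the mean differed in sign for immune effectors (0.12 and -0.03), the irld family (-0.22 and 1.11) and glycolysis (0.09 and -0.06). For insulin signalling, dauer pathway and oxidative phosphorylation genes the median, mean and set test, all near 0, did not share a sign.

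In edgeR against a 1.5-fold change 369 genes passed in the daf-2 mutant, and in a fit of these groups alone 1208. The daf-2 libraries that stood apart on the first component bear on several of these groups: without daf-2 replicates 2 and 4, and without the low library of LRB458, collagen genes counted 38 higher and 5 lower, cytochrome P450 genes 29 and 1, glutathione S-transferase genes 18 and 2 and UDP-glycosyltransferase genes 16 and 6. Autophagy genes then counted 2 lower, lysosomal genes 8 lower and neuropeptide genes 4 higher and 25 lower. With the mean level of the full early embryo list as a term in the model, 55 of 78 ribosomal protein genes were lower, and 4 glutathione S-transferase and 8 cytochrome P450 genes were higher.

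**Figure D2:**
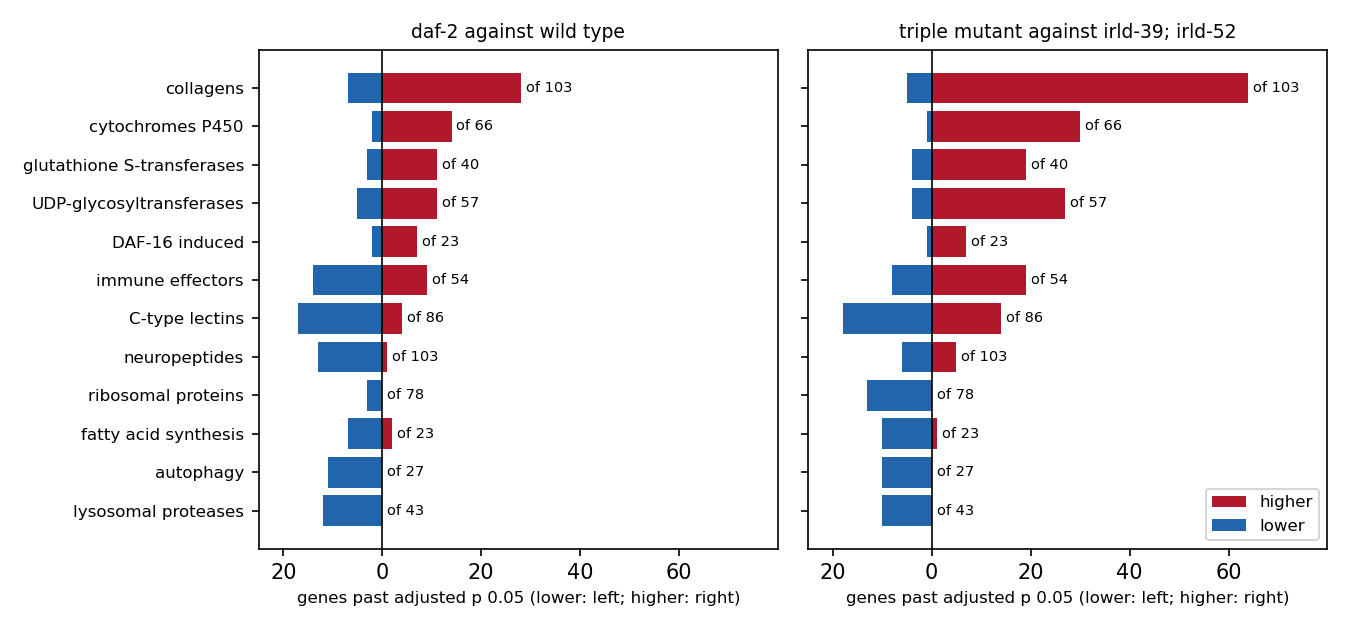
Number of genes per fixed list past an adjusted p of 0.05, higher (right) or lower (left), in the daf-2 mutant against wild type and in the triple mutant against the irld mutant; the number beside each bar is the number of genes tested. Collagen genes counted 28 higher and 7 lower in the left panel and 64 higher and 5 lower in the right panel.

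The triple mutant was compared with the daf-2 mutant to describe the irld alleles where daf-2 is mutant. Several genes that were higher in the daf-2 mutant than in wild type were lower in the triple mutant than in the daf-2 mutant. For irld-53 the triple mutant held 9 counts against 2152 in the daf-2 mutant, so that the daf-2 libraries were 273 times higher (95% counting interval 143 to 597), and for irld-35 it held 16 against 2005 counts (143 times, 87.8 to 251), with adjusted p = 8.25e-09 and 2.46e-09. F56A4.2 (WBGene00018910, chromosome V, 2459637 to 2460893) fell from 45.7 ± 7.43 to 1.35 ± 0.560 CPM (-5.04 ± 0.32, adjusted p = 1.85e-07) and the C-type lectin gene clec-209 (WBGene00021224, chromosome V, 2351676 to 2352932) from 46.2 ± 5.45 to 1.53 ± 0.641 CPM (-4.87 ± 0.31, 1.85e-07). In wild type F56A4.2 and clec-209 stood at 22.2 ± 8.18 and 20.97 ± 7.29 CPM, above the triple mutant. The chemoreceptor-like gene srw-85 (WBGene00005832, chromosome V, 19429387 to 19431136) rose from 2.195 ± 0.705 CPM in the daf-2 mutant to 134 ± 7.12 CPM in the triple mutant (5.94 ± 0.30, 8.25e-09).

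In all, 2 genes were higher and 11 lower of 14058, with 915 genes at an unadjusted p under 0.05. Also lower were F56A4.3 (-2.40 ± 0.25, adjusted p = 8.56e-05), Y45G12C.16 (-1.07 ± 0.11, 1.06e-04) and C13B7.6 (-1.04 ± 0.11, 1.20e-04). The gene Y43F8C.3 was higher (0.85 ± 0.14, adjusted p = 0.0157), a call lost without daf-2 replicate 1, 2 or 3 or replicate 1 of LRB457, where adjusted p reached 0.0768. The other called genes, srbc-15, C01B4.6, Y19D10A.16 and ZC190.8, were lower and fall outside the rule for named genes; they are named after their values were seen. All 13 lie on chromosome V, which holds 21.2% of the tested genes. They are not spread evenly along it. The genes irld-53, clec-209, C13B7.6, F56A4.3, irld-35, F56A4.2 and Y45G12C.16 all lie between positions 2348215 and 2531174. Another close pair is srw-85 and Y43F8C.3, which start at 19429387 and 19614506. The 13 genes therefore cannot be counted as independent. Pairs among them have the same annotated length, and reads that match a pair of places were placed at one of them, so how counts divide within a pair is uncertain. DESeq2 called 27 genes and edgeR against a 1.5-fold change 7.

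The DAF-16 target sod-3 differed by -0.10 ± 0.23 between the triple and the daf-2 mutant (adjusted p = 0.964), mtl-1 by -0.15 ± 0.19 (0.911), hsp-12.6 by -0.09 ± 0.26 (0.977), daf-16 by -0.06 ± 0.15 (0.965) and daf-28 by 0.07 ± 0.41 (0.992), none of them called. Of the lists, 11 passed camera, and none with an estimated correlation. Ribosomal proteins were lower as a set (median -0.22, adjusted p = 1.10e-18; adjusted p = 0.731 with an estimated correlation) and so were cell cycle genes. Collagens were higher as a set (median 0.29, adjusted p = 1.04e-07; adjusted p = 0.731 with an estimated correlation), as were pharynx markers (median 0.52, 2.15e-06; 0.446), UDP-glycosyltransferases, cytochromes P450, immune effectors, heat shock, hypoxia and molting genes. In the irld family 2 of 15 genes fell, irld-53 and irld-35, also when adjusted over the list alone (set adjusted p = 1.04e-04; adjusted p = 0.0970 with an estimated correlation). Adjusted over the list alone, 2 UDP-glycosyltransferase genes and 1 molting gene were higher. For the lists given without values, adjusted p lay between 0.469 and 0.802 with an estimated correlation. By fry, which tests whether a set moves one way, 1 list passed.

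**Figure D3:**
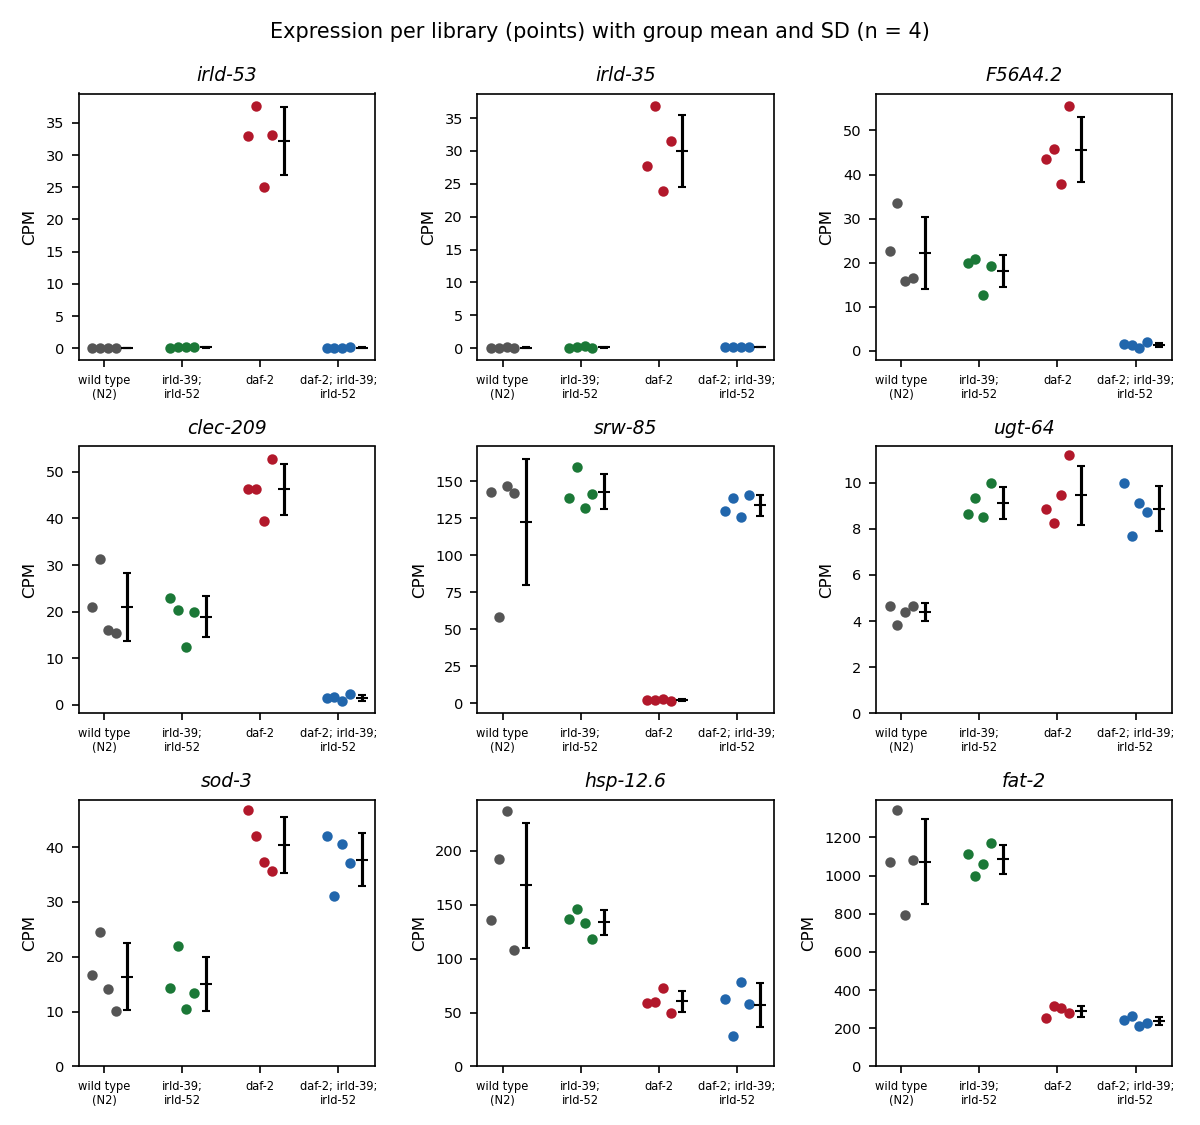
CPM per library (points) with group mean and SD (n = 4) for 9 genes in the 4 genotypes. The genes irld-53, irld-35, F56A4.2 and clec-209 are highest in the daf-2 mutant, and srw-85 is at 2.195 CPM there against 122 to 143 CPM in the other genotypes.

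The interaction asks whether the irld alleles change a gene differently with and without the daf-2 allele. It was negative for irld-53 (-10.67 ± 1.202, adjusted p = 4.52e-04), irld-35 (-7.66 ± 0.87, 4.52e-04), F56A4.2 (-4.75 ± 0.40, 1.92e-05) and clec-209 (-4.72 ± 0.39, 1.92e-05), with the values of irld-53 and irld-35 resting on few counts outside the daf-2 mutant. It was smaller for Y45G12C.16 (-1.31 ± 0.16, 0.00121) and C13B7.6 (-1.19 ± 0.16, 0.00299). It was positive for srw-85 (5.72 ± 0.37, adjusted p = 9.20e-07). For ugt-64 it was -1.15 ± 0.18 (adjusted p = 0.0139): the gene stood at 4.39 CPM in wild type and at 9.12, 9.45 and 8.88 CPM in the irld, daf-2 and triple mutants. This call was lost without irld replicate 4, LRB457 replicate 3 or replicate 1 or 4 of LRB458, with adjusted p up to 0.0634. For ttr-50, a transthyretin-related gene (WBGene00010234, chromosome IV, 11640047 to 11641015), it was 2.33 ± 0.37 (adjusted p = 0.0197), lost in 10 of the 16 fits that leave out 1 library, namely without wild-type replicate 1, 2 or 3, any daf-2 replicate, irld replicate 4, LRB457 replicate 3 or LRB458 replicate 4, with adjusted p up to 0.0768.

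These 9 genes, 2 positive and 7 negative, are all the interaction called of 14058, with 844 at an unadjusted p under 0.05. DESeq2 called 22 and edgeR against a 1.5-fold change 5. The interaction was not called for sod-3 (0.03 ± 0.33, adjusted p = 0.985), mtl-1 (0.50 ± 0.27, 0.763), hsp-12.6 (0.24 ± 0.37, 0.855), daf-16 (-0.41 ± 0.21, 0.763), daf-28 (0.17 ± 0.59, 0.944) or daf-2 (-0.45 ± 0.31, 0.768). The authors' deposited table of the interaction lists 12690 genes and puts 9 past an adjusted p of 0.05, the same 9, with fold changes of opposite sign (Pearson r = -0.9999 across genes, which are not independent replicates). Of the lists, 8 passed camera and the irld family alone passed with an estimated correlation. In this family 2 of 15 genes, irld-53 and irld-35, were called, also when adjusted over the list alone. The set had an adjusted p = 9.21e-07 by camera and adjusted p = 0.0195 with an estimated correlation. Both genes have the same annotated length and few counts outside the daf-2 mutant, so they may not be separate signals. Whether the set passes without them was not tested. Collagens (adjusted p = 1.03e-12; adjusted p = 0.560 with an estimated correlation), immune effectors (9.21e-07; 0.713), neuropeptides (2.36e-06; 0.713), pharynx markers (0.00151; 0.713), UDP-glycosyltransferases (0.0128; 0.713), insulin-like peptides (0.0339; 0.713) and glutathione S-transferases (0.0339; 0.843) were positive as sets. The 1 called gene among their members, ugt-64, was negative. By fry 1 list passed.

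The triple mutant was compared with the irld mutant to describe the daf-2 allele where the irld genes are mutant. Collagen genes rose widely: 64 were higher and 5 lower (71 higher and 8 lower when adjusted over the list alone), with col-42 going from 2643 ± 646 to 7259 ± 529 CPM (1.46 ± 0.17) and col-180 at 1.79 ± 0.21 (set adjusted p = 1.11e-17; adjusted p = 0.266 with an estimated correlation). Of the detoxification enzymes, 30 of 66 cytochrome P450 genes rose and 1 fell (set adjusted p = 7.36e-08; adjusted p = 0.516 with an estimated correlation), 27 of 57 UDP-glycosyltransferase genes rose and 4 fell (5.84e-05; 0.266) and 19 of 40 glutathione S-transferase genes rose and 4 fell (1.27e-04; 0.583). Adjusted over the list alone, these were 36 higher and 2 lower, 29 higher and 7 lower and 23 higher and 4 lower. Molting genes of the cuticle rose, mlt-8 by 2.56 ± 0.32, noah-2 by 2.87 ± 0.39 and mlt-11 by 2.70 ± 0.40, with 7 of 23 higher and 1 lower (7 higher and 1 lower when adjusted over the list alone); the set did not pass (adjusted p = 0.0834).

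Of DAF-16 induced genes 7 of 23 rose and 1 fell (9 higher and 1 lower when adjusted over the list alone; set adjusted p = 0.00311; adjusted p = 0.583 with an estimated correlation). The glyoxylate cycle gene icl-1 rose from 77.3 ± 22.2 to 365 ± 119.4 CPM (2.24 ± 0.33) and sod-3 by 1.33 ± 0.24 (adjusted p = 0.00119), and hsp-12.6 fell (-1.24 ± 0.27, 0.00453). The metallothionein gene mtl-1 was higher (0.65 ± 0.19, adjusted p = 0.0260), a call lost without irld replicate 3 or 4, LRB457 replicate 3 or LRB458 replicate 4, with adjusted p up to 0.0748. Neither daf-16 (-0.24 ± 0.15, adjusted p = 0.291) nor daf-28 (0.30 ± 0.42, 0.687) was called. Of immune effector genes 19 of 54 rose and 8 fell (24 higher and 9 lower when adjusted over the list alone; set adjusted p = 0.0245; adjusted p = 0.583 with an estimated correlation), with the lysozyme gene lys-2 higher (2.60 ± 0.32) and the saposin-like genes spp-6 and spp-17 lower (-2.36 ± 0.31 and -3.40 ± 0.54). Autophagy genes fell in 10 of 27 cases (set adjusted p = 5.84e-05; adjusted p = 0.266 with an estimated correlation), lysosomal genes in 10 of 43 (0.00334; 0.583), fatty acid synthesis genes in 10 of 23 with 1 higher (0.00254; 0.517), and fat-2 fell to 238 ± 21.1 CPM (-2.19 ± 0.14). Adjusted over the list alone these were 0 higher and 14 lower, 1 higher and 12 lower and 4 higher and 13 lower. In the irld family 5 of 15 genes were lower (6 when adjusted over the list alone), irld-24 by -0.92 ± 0.23 (set adjusted p = 0.0202; adjusted p = 0.266 with an estimated correlation).

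In this comparison 1378 genes were higher and 1215 lower of 14058, of which 824 and 294 were over 2-fold. With library sizes of all reads 1689 were higher and 877 lower, and with the early embryo term 1431 and 1426. The largest changes were rises of F57H12.6 to 152 ± 120.1 CPM (8.51 ± 1.68), C45B2.3 to 21.4 ± 19.04 CPM and E02C12.10 to 22.9 ± 23.4 CPM, the last 2 from at most 0.127 CPM, and falls of dod-24 (-6.24 ± 0.44), F56A4.2 (-3.71 ± 0.31) and clec-209 (-3.58 ± 0.30). Without LRB458 replicate 4 the change of dod-24 was -7.01. Ribosomal proteins were lower as a set (median -0.31, adjusted p = 1.25e-11; adjusted p = 0.583 with an estimated correlation), with 13 of 78 called and 42 when adjusted over the list alone. Of the 20 lists that passed camera, those not yet named were heat shock, antioxidant, proteasome, oxidative phosphorylation, insulin-like peptide and hypodermis marker genes, higher, and neuron marker, histone and DAF-16 repressed genes, lower. Their adjusted p lay between 0.266 and 0.617 with an estimated correlation, and the DAF-16 repressed list had a median of 0.41 against a mean of -1.42. Without the 3 libraries low on the first component, collagen genes counted 67 higher and 4 lower, cytochrome P450 genes 34 and 1, glutathione S-transferase genes 25 and 2, and ribosomal protein genes 1 lower. The total was 691 against a 1.5-fold change, 1379 without the libraries of LRB457 and 1496 without those of LRB458.

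Against wild type, the triple mutant shows all the alleles together. Ribosomal protein genes fell in 62 of 78 cases and none rose (68 lower when adjusted over the list alone), with rpl-26 going from 1577 ± 147 to 1079.8 ± 50.2 CPM (-0.55 ± 0.11) and rps-19 at -0.61 ± 0.13 (set adjusted p = 2.56e-20; adjusted p = 0.409 with an estimated correlation). Collagen genes counted 51 higher and 7 lower (63 higher and 8 lower when adjusted over the list alone; set adjusted p = 4.65e-10; adjusted p = 0.393 with an estimated correlation), although dpy-5, a collagen gene that shapes the body, fell from 105 ± 95.0 to 7.02 ± 4.05 CPM (-3.93 ± 0.80). Cytochrome P450 genes counted 32 higher and 3 lower (adjusted p = 1.46e-07; adjusted p = 0.409 with an estimated correlation), UDP-glycosyltransferases 28 and 6 (1.42e-04; 0.393) and glutathione S-transferases 18 and 5 (0.00780; 0.818), with gst-4, a gene of the oxidative stress response, at 6.63 ± 2.82 CPM in wild type and 61.3 ± 43.5 CPM in the triple mutant (3.21 ± 0.64). Adjusted over the list alone, these were 36 higher and 3 lower, 31 higher and 6 lower and 22 higher and 5 lower. The DAF-16 targets sod-3 and icl-1 rose (1.201 ± 0.24 and 1.53 ± 0.32; adjusted p = 0.00250 and 0.00416) and hsp-12.6 fell (-1.57 ± 0.27, 8.90e-04), while mtl-1 (-9.45e-04 ± 0.19, 0.999), daf-16 (0.10 ± 0.15, 0.677) and daf-28 (0.20 ± 0.42, 0.780) were not called.

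In all 1413 genes were higher and 1458 lower than in wild type, 733 and 373 of them over 2-fold. With library sizes of all reads 1802 were higher and 1067 lower, and with the early embryo term 1051 and 1580. The largest changes were again rises of C45B2.3, E02C12.10 and F57H12.6 (7.71 ± 1.58) and falls of dod-24 (-6.37 ± 0.44) and F56A4.2 (-3.998 ± 0.31); C45B2.3 and E02C12.10 stood at 0.0344 and 0.0515 CPM in wild type, so that their fold is not given. The change of F57H12.6 was 8.41 without wild-type replicate 3, and that of dod-24 was -7.15 without LRB458 replicate 4. Of the 17 lists that passed camera, those not yet named were molting, body muscle, hypodermis, heat shock, endoplasmic reticulum stress and DAF-16 induced genes, higher, and neuropeptide, lysosomal, autophagy, histone, fatty acid synthesis and DAF-16 repressed genes, lower. Their adjusted p lay between 0.156 and 0.738 with an estimated correlation, and the DAF-16 repressed list had a median of 0.46 against a mean of -1.56. With the full early embryo list as a term in the model, collagen genes counted 31 higher, cytochrome P450 genes 14, glutathione S-transferase genes 7 and ribosomal protein genes 72 lower. The total was 623 against a 1.5-fold change, 1390 without the libraries of LRB457 and 1552 without those of LRB458.

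The effects of the daf-2 allele with and without the irld alleles shared most of their direction. Of the genes called in both comparisons, 639 were higher in both, against 110 if calls were independent, 705 were lower in both, against 94.0, and 2 had opposite directions. Across the 14058 tested genes, which are not independent replicates, the fold changes of these comparisons, which share no library, had a Pearson r of 0.763. The effects of the irld alleles with and without the daf-2 allele, which also share no library, had a Pearson r of -0.104 across genes. In an exact permutation test of the same correlation on mean log2 CPM (r = -0.128), 1856 of 4900 assignments of libraries were at least as far from 0 (two-sided p = 0.379). The irld and daf-2 effects against wild type share the wild-type libraries. Their fold changes had a Pearson r of 0.213 and a covariance of 0.0469 across genes, against means of 0.506 and 0.0487 in 20 simulations of unchanged groups that share these libraries. With wild type split so that each effect had its own 2 libraries, r averaged -0.0108 over 6 splits (-0.109 to 0.0763). One gene was called in both, ugt-64, higher in each; both calls rest on the same wild-type libraries. The simulations gave 0 shared calls from a mean of 0.3 calls in 1 comparison, too few to test this.

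The 2 lines of the triple mutant were compared with each other within the same model. No gene differed between LRB458 and LRB457 by edgeR, with 349 genes at an unadjusted p under 0.05 and 2 libraries per line. Against the irld mutant 1470 genes were called for LRB457 and 1573 for LRB458, and against the daf-2 mutant 9 and 12; the lines share these control libraries. In both lines irld-35 (-6.89 and -7.39), F56A4.2 (-5.44 and -4.78) and clec-209 (-5.42 and -4.53) were below the daf-2 mutant, and srw-85 was above it (5.87 and 6.002), each called in both.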

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

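The tests of explanations and the reshuffled groupings in this part were chosen after the results were seen. The interaction was significant for 9 genes: the difference between strains with and without the irld alleles was not the same with and without daf-2(e1370), with log2 differences of 5.72 for srw-85, 2.33 for ttr-50, -1.15 for ugt-64, -1.19 for C13B7.6, -1.31 for Y45G12C.16, -4.75 for F56A4.2, -4.72 for clec-209, -7.66 for irld-35 and -10.67 for irld-53.

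The first pattern is the set of 13 genes that differ between the triple and the daf-2 mutant. All 13 of 13 lie on chromosome V, where 21.2% of the tested genes lie. Variants on chromosome V that differ between the strains cannot be told apart from other causes by this count. The chromosome was picked from the result, and the genes cannot be counted as independent. Several are neighbours between positions 2348215 and 2531174, and some form pairs of equal length. Of the genes called in the daf-2 mutant against wild type, 556 of 2209 lie on V. The 4 pairs of gene copies of equal length were picked from genes already called lower, so lower members and sums in 4 of 4 pairs followed from this choice. Their summed counts changed by -7.60 ± 0.31, -4.97 ± 0.32, -1.06 ± 0.0913 and -1.37 ± 0.18 (log2 fold change ± standard error). Reads moving between the copies of a pair would leave its sum unchanged, so this alone does not account for the sums of these pairs. Since the choice of pairs fixed the outcome, it is no test of that cause for other genes. That the genes are copies was taken from their equal annotated length, and their sequences were not compared. A called gene whose copy was not called could not enter this comparison. Whether 1 or both copies of a pair changed was not tested, and the other 5 genes are in no such pair. An effect of the irld alleles where daf-2 is mutant stays open, since with 1 daf-2 strain it cannot be told apart from strain variants. All 13 genes moved the same way in both lines, which decides nothing, since they were called on the mean of both lines against the same daf-2 libraries.

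The second pattern is the wide spread of the 8 libraries with daf-2(e1370) on the first component. For a day or batch shared by equal replicate numbers, 1 of 4 same-numbered pairs of daf-2 and triple mutant libraries had a correlation over 0.1 (-0.462 to 0.147). This gives no sign of a batch, but 4 pairs, 2 of which share daf-2 replicate 1, cannot exclude it. Over all groups 9 of 24 same-numbered pairs passed 0.1, against 18 of 72 with different numbers. RNA of early embryos in some libraries is a candidate explanation: the component correlated with the mean of 20 early embryo genes, a list from which genes already seen to vary were left out (Pearson r = -0.893, exact permutation p = 0.00342, 0.00685 adjusted over 2 relations; -0.778 without the 2 farthest libraries). It stays open, since of its 4 most abundant genes spn-4 (r with the component = -0.956), mex-3 (-0.739) and tbg-1 (-0.453) fell along the component but skn-1 did not (0.435), and wild-type and irld libraries span 2.48 to 3.32 in the list at nearly 1 place on the component. A difference between the triple mutant lines is argued against as the whole cause: the 4 daf-2 libraries, which are 1 strain, span 53.8 on the component and those of LRB458 42.4, against 7.999 between the means of the lines.

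Other groupings of the same libraries were tried, 35 for each pair of groups and 100 for the interaction. The smallest share that 35 can give is 1 of 35, and shares were not adjusted over the contrasts. For genes, no other grouping came near the count of the daf-2 mutant against wild type (1 of 35 as large, 2209 genes, highest other 1). The same held for the triple against the irld mutant (1 of 35, 2593, highest other 6) and the triple mutant against wild type (1 of 35, 2871, highest other 0). Not adjusted over the contrasts, a share of 1 of 35 does not by itself exclude chance. Other groupings gave at least as many genes for the irld mutant against wild type (2 of 35, 1 gene, highest other 2) and the triple against the daf-2 mutant (2 of 35, 13, highest other 308). They also did for the interaction (6 of 100, 9, highest other 74), so chance cannot be excluded for the number of genes in these contrasts. The 308 genes come from setting daf-2 replicates 1, 2 and 4 with LRB458 replicate 1 against the rest, which points to a structure of the samples. These counts do not test single genes: irld-53 stood at 25.1 to 37.7 CPM in the daf-2 libraries against 0 to 0.232 in the triple mutant, and srw-85 at 1.27 to 2.98 against 126 to 141. For lists, no other grouping gave as many for the triple against the irld mutant (1 of 35, 20 lists, highest other 17), although 0 passed with an estimated correlation. This share is not adjusted over the contrasts, and other groupings reached 20 lists in the daf-2 mutant and the interaction, so chance was not excluded. It cannot be excluded for the irld mutant (8 of 35; 11, highest other 14), the daf-2 mutant (11 of 35; 13, 20), the triple against the daf-2 mutant (20 of 35; 11, 17), the triple mutant against wild type (2 of 35; 17, 17) or the interaction (75 of 100; 8, 20).

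The share of unaligned reads in 1 daf-2 library lay far from the other 3 (gap to the nearest other over the range, 0.840). For the named genes, 1 library lay far from the others in 29 of 340 combinations of gene and group, where chance gives about 1 in 20 (17). In wild type these were, with the same ratio, C45B2.3 (1), E02C12.10 (1), Y45G12C.16 (0.901), cpr-1 (0.852), elo-5 (0.867), fat-3 (0.890), ins-7 (0.969), irld-35 (0.945), irld-53 (1), mtl-2 (0.848), nlp-77 (0.836), nuc-1 (0.856), spp-6 (0.862) and srw-85 (0.95). In the irld mutant these were, with the same ratio, cpr-1 (0.851), daf-16 (0.901), daf-2 (0.842), dod-24 (0.843), icl-1 (0.851), lipl-5 (0.955) and noah-2 (0.976). In the daf-2 mutant these were, with the same ratio, cpr-1 (0.914), dpy-5 (0.917), nlp-77 (0.904), spp-17 (0.833) and spp-6 (0.942). In the triple mutant these were, with the same ratio, catp-3 (0.839), rps-19 (0.860) and tps-1 (0.856). The genes C45B2.3, E02C12.10, ins-7, irld-35 and irld-53 reached at most 0.206 CPM in any wild-type library. There the ratio rests on few counts, and the chance share of 1 in 20 need not hold.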

How the results depend on the processing

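Alternatives chosen after the data were seen were protein-coding genes alone, all-read library sizes, the early embryo term, leaving out 3 libraries and, for lists, leaving out each library; the 3 libraries were chosen by their place on the first component, so leaving them out moves the groups apart by construction. Of 370 named results past the threshold, 260 stayed past it under every alternative but the 1.5-fold test, and in 7592 comparisons 6850 were kept, 742 lost and 0 reversed. The 1.5-fold test asks a stricter question and gave lower counts (0 in the irld mutant, 369 in the daf-2 mutant, 7 in the triple against the daf-2 mutant, 691 against the irld mutant, 623 against wild type, 5 in the interaction). Counts were also lower with fewer libraries, without LRB457 (1379 against the irld mutant, 1390 against wild type) or LRB458 (1496 and 1552). Whether the number of libraries or the line lowered them was not tested, nor was the cause of the other differences. With only the groups compared, 0 genes passed in edgeR in the irld mutant (911 at an unadjusted p under 0.05 in the full model; DESeq2 2) and 1208 in the daf-2 mutant. Replicate numbers were not taken to pair the libraries, and whether equal numbers share a batch stays open. A correlation of residuals over 0.1 was found in 9 of 24 same-numbered pairs, against 18 of 72 with different numbers. Between wild type and the irld mutant 3 of 4 pairs passed (0.176, 0.187 and 0.183, with -0.149 for number 1). Of 16 libraries, 8 correlated best with their own number, for which no chance value was computed. With the replicate block the irld mutant had 2. DESeq2 gave 2 in the irld mutant, 27 in the triple against the daf-2 mutant and 22 in the interaction. With the estimated correlation 0 lists passed in 5 contrasts and 1 in the interaction, and by fry 0 in the irld mutant, 1 in the triple against the daf-2 mutant and 1 in the interaction. Leaving out 1 library gave 1 to 1 genes in the irld mutant, 1542 to 2187 in the daf-2 mutant, 11 to 13 in the triple against the daf-2 mutant, 1891 to 2390 against the irld mutant, 2057 to 2745 against wild type and 7 to 13 in the interaction. For lists the ranges were 9 to 13, 11 to 18, 8 to 17 (17 without daf-2 replicate 3), 16 to 22, 14 to 17 and 5 to 14 (14 without wild-type replicate 1 or daf-2 replicate 3, 5 without LRB457 replicate 3). The correlation of the irld and daf-2 effects was 0.319 over genes called in either, -0.0108 with wild type split, and 0.153 (without irld replicate 2) to 0.313 (without wild-type replicate 4). That of the irld effect in 2 backgrounds was -0.450 over the 14 genes called in either, -0.148 with the block, and -0.200 (without irld replicate 3) to -0.0351 (without irld replicate 2), with -0.0492 without daf-2 replicate 1 and -0.0376 without wild-type replicate 3. None of the changes of sign below was in a called value. In the irld mutant daf-28 was 0.13 with the embryo term (-0.34 to 0.18 leaving out 1 library) and sod-3 ranged from -0.37 to 0.13. In the daf-2 mutant daf-28 was -0.56 without 3 libraries (-0.28 to 0.39), mtl-1 ranged from -0.0467 to 0.25 and daf-2 from -0.0396 to 0.33. Between the triple and the daf-2 mutant, sod-3 was 0.00969 with the block and 0.0569 without LRB458 (-0.16 to 0.00235), hsp-12.6 0.25 without LRB458 and 0.0416 without 3 libraries (-0.26 to 0.16), daf-16 0.0476 and 0.0675 (-0.0936 to 0.0117) and daf-28 -0.36 without LRB457 (-0.19 to 0.49). Between the triple and the irld mutant daf-28 was -0.13 without LRB457. Between the triple mutant and wild type, mtl-1 was 0.0747 with the block, 0.00971 with DESeq2 size factors, 0.00971 with DESeq2, 0.0504 without LRB458, 0.00453 with protein-coding genes, 0.0747 with all-read sizes and 0.0594 without 3 libraries (-0.20 to 0.0984). There daf-28 was -0.23 and daf-2 -0.0672 without LRB457 (daf-2 -0.17 to 0.20), and daf-16 ranged from -0.0572 to 0.20. In the interaction, without LRB457, sod-3 was -0.12 (-0.23 to 0.27), hsp-12.6 -0.14 and daf-28 -0.26 (-0.11 to 0.61). Depth limits irld-39, irld-52 and ins-7, whose counts are too few to test. Scaling by spike-ins was not run.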

Other observations

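No test in this part was added after the results were seen. Markers of tissues and stages were tested as lists, and their values in the daf-2 mutant against wild type are given as genes higher and lower. Body muscle markers counted 3 and 0 of 20 (set adjusted p = 0.00457; adjusted p = 0.551 with an estimated correlation), with the muscle gene dim-1 at 0.79 ± 0.12, and pharynx markers 0 and 1 of 18 (0.0308; 0.602). The other lists did not pass as sets. Intestine markers counted 1 and 3 of 19, with the intestinal actin gene act-5 higher (1.05 ± 0.15) and the gut esterase gene ges-1 lower (-0.84 ± 0.11). Hypodermis markers counted 2 and 0 of 17, with the hedgehog-related gene grd-10 at 1.92 ± 0.21. Primordial germline markers counted 5 and 0 of 19, with prg-1 at 0.96 ± 0.16. Neuron markers counted 0 and 0 of 25, embryo markers 0 and 0 of 13, adult oocyte markers 0 and 0 of 17 and sperm markers 0 and 0 of 12. The sperm list had a median of 0.15 and a mean of -0.10. Dauer markers counted 2 and 2 of 12. Adjusted over the list alone the counts were the same except for dauer markers (3 higher and 2 lower).

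Per the labels, 2 libraries of the triple mutant are numbered 1 and 0 are numbered 2.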
